A study of Rattus norvegicus and Mus musculus with 107 samples.

How the data were processed

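Chromatin immunoprecipitation sequencing of CREB, CRTC2, CBP, BRD4, NeuroD1, PDX1, H3K27ac and RNA polymerase II was deposited for INS-1 and AR42J cells, mouse islets and mouse hepatocytes. Per the submitters' processing notes, Bowtie2, STAR and HOMER were used with the builds rn5, rn6 and mm10; the notes do not say which tool or build belongs to which file. Per the file headers, 42 peak lists were called in HOMER's factor style, 40 in its histone style and 4 as super-enhancers, with at least 4-fold over the input library and, for factor lists, a false discovery rate of 0.001. The deposited peak lists hold coordinates of intervals, and their scores were not used. Peak number, base pairs covered and shares of sites with a peak were computed here from those coordinates. Depth is the total of tags in each header, from 6.15 to 35.0 M over 82 lists; 6 islet lists state none.

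Per the readme, the authors counted H3K27ac tags in 4000 bp windows, 2000 bp either side of CREB peaks of forskolin replicate 1, and compared the arms with HOMER and DESeq2. The deposited table calls its per-library values tag counts, but they hold decimals and negative values, and the authors' values lie on a log2 scale whose exact transformation is not stated. The plan made before the data were examined assumed counts, so limma was used on these log2 values instead. A change in them is not a fold change: its slope on the authors' log2 fold change was 0.62 (r = 0.98). The deposited table also gives the authors' own log2 fold changes and adjusted p-values, which served for comparison only.

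Rat peak lists were checked against H3K27ac peaks of control replicate 1. H3K27ac lists on the same build met 30.0% to 100% of their peaks there and other lists 52.5% to 98.4%, while 4 H3K27ac lists of wild-type and SYT7eDel cells met 5.54% to 5.78% and were kept apart as another rat build. The table's coordinates are on the build of the former lists, taken as rn5, and mouse lists were taken as mm10. Of the nearest genes, 10260 were named through their RefSeq accession and 731 as the table gives them, since 19 names had turned into dates.

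Samples were grouped by cell, target, virus or drug, and treatment. In the main test, limma 3.58.1 with empirical Bayes compared 4 forskolin with 4 control libraries at 10991 sites, with Benjamini-Hochberg adjustment and a threshold of 0.05. The values were not scaled again. Nothing states that the replicates are separate cultures, so p-values measure spread between these samples. Same-numbered control and forskolin libraries had residuals with correlations of 0.657, 0.649, 0.765 and 0.750, against −0.603 to 0.397 for other numbers, so the numbers were also used as a block. Tested on simulated data, the procedure recovered 2.99% of log2 changes of 0.25, 58.2% of 0.5 and 92.4% of 1. Changes were added to 200 of 10991 sites, and 11 of the unchanged sites were called falsely. The simulation used the test without the block, drew each library independently and did not vary depth. Same-numbered libraries were therefore not alike in it, as they were in the data. It changed far fewer sites than were called in the data (3416), which makes the adjusted threshold stricter, so its recovery may not carry over.

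Gene lists were fixed before the data were examined: 7 lists, of CREB targets, beta-cell identity, secretion machinery, hepatocyte and fasting, acinar, other islet cells, and housekeeping genes. Each was tested at the CREB sites nearest to its genes with camera (preset correlation 0.01, and with an estimated correlation) and fry. The named sites are the 12 largest called changes in each direction, up to 8 called members per list, and all sites of a fixed set of genes (Fos, Nr4a1, Per1, Crem, Sik1, Ins1, Ins2, Pdx1, Neurod1, Syt7, Pck1, G6pc and Actb). For peak lists, up to 4 members per outcome were named, in list order. A gene's peak outcome was read at its nearest CREB site within 100 kb.

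A site or window had a peak when they shared at least 1 bp. Alternatives were an overlap of at least 50% of the shorter interval, centres within 500 bp, and lists drawn at random to equal length. Such a draw lowers the shares of the longer list by itself. It therefore cannot tell a loss of peaks from a difference in list length. Classes of co-bound factors were joined by an overlap of at least 1 bp, with centres within 200 bp as an alternative. By the overlap, 5 sites lay in several classes. Classes were compared by permutation of labels (100000 resamples, seed 11) and groups of 4 by exact permutation over 70 regroupings. Pairs were compared by exact sign flips and peaks across sites or genes by Fisher's exact test; all tests were two-sided. Intervals of shares are 95% Wilson intervals, and the interval of a difference of medians came from 10000 bootstrap resamples. Alternatives planned before the data were examined numbered 53, and those added afterwards are described as such.

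Groups of 1 library have no estimate of spread. Inputs and RNA polymerase II libraries outside the Syt7 experiment were not used here. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and R 4.3.3.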

Results

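The series asked how CREB, the transcription factor activated by cAMP, acts on chromatin in insulin-producing cells, in an exocrine pancreatic line and in liver cells. It held 107 chromatin immunoprecipitation (ChIP-seq) samples in 93 groups. Of these, 85 came from INS-1 cells (a rat insulinoma line), 6 from AR42J cells (a rat pancreatic acinar line), 8 from cultured mouse islets and 8 from mouse hepatocytes. Forskolin, which activates adenylyl cyclase and so raises cAMP, was given at 10 µM for 1 hour where the labels state a dose. CREB and H3K27ac, the histone acetylation of active enhancers and promoters, had 4 control and 4 forskolin libraries each in INS-1 cells. BRD4, a reader of acetylated chromatin, had 2 of each, and the other 87 groups held 1 library. Peak lists of 88 samples were used, and the other 19 samples, the inputs and most RNA polymerase II libraries, were not analysed here. Library depth, where a list stated it, ran from 6.15 to 35.0 M tags with a median of 19.2 M (M, mega). Values from groups of 1 library have no replicate error, and their intervals are 95% Wilson intervals that cover counting error only. Tests across sites in such groups compare those libraries, since sites are not replicates.

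Forskolin changed H3K27ac in both directions at the sites that CREB occupied in forskolin-treated INS-1 cells. H3K27ac rose at 1987 and fell at 1429 of 10991 CREB sites (limma, 4 libraries against 4, adjusted p under 0.05 over all sites). Values are the deposited log2 levels over 4000 bp, and the libraries behind them held 11.4 to 25.6 M tags. Pde4d, which encodes a cAMP phosphodiesterase, rose from 6.57 ± 0.18 to 8.56 ± 0.081 (SD, n = 4 each; adjusted p = 2.15e-06) at an intronic site on rat chromosome 2, 60343099 to 60347099 (rn5). An intronic site of Pde10a, another phosphodiesterase gene, rose from 8.70 ± 0.23 to 10.24 ± 0.27 on chromosome 1, 53726020 to 53730020. The sharpest fall lay 54203 bp from the start of Sst, the somatostatin gene, where H3K27ac went from 8.20 ± 0.54 to 6.54 ± 0.28 (adjusted p = 3.86e-04; chromosome 11, 80319334 to 80323334). The promoter of Txnip, which encodes a thioredoxin-binding protein, fell from 9.80 ± 0.18 to 8.61 ± 0.30.

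The 12 largest rises, all adjusted p at or under 3.97e-04, were nearest to Mtarc1 (log2 change 2.34), Trak1 (2.23), Zfp612 (2.19), Large1 (2.15), LOC108348453 (2.03), Pde4d (1.99), Ndufs4 (1.96), Sv2c (1.95), Sdcbp (1.90), Tgds (1.85), Babam2 (1.85) and Rcn1 (1.84). The Zfp612 site was a promoter, and the Sv2c site, near a synaptic vesicle protein gene, lay 1342 bp from the start. The 12 largest falls were nearest to Sst (−1.66), Grk3 (−1.41), Aoah (−1.39), Slc1a1 (−1.28), Serbp1 (−1.27), Abra (−1.24), Shank2 (−1.22), Kcnq5 (−1.21), Dkk3 (−1.20), Txnip (−1.18), Oxr1 (−1.18) and Cog6 (−1.17). Called sites were fewer at promoters. Of 4861 sites within 1 kb of a gene start, 7.32% rose and 11.0% fell, against 28.8% and 17.2% of the 1561 sites more than 100 kb away. Among the 25% of sites with the lowest control H3K27ac, 806 rose and 147 fell, and in the highest 25%, 301 rose and 450 fell. The control level is also part of each change, so noise alone tends to give rises at low and falls at high sites. That part was not separated.

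**Figure D1:**
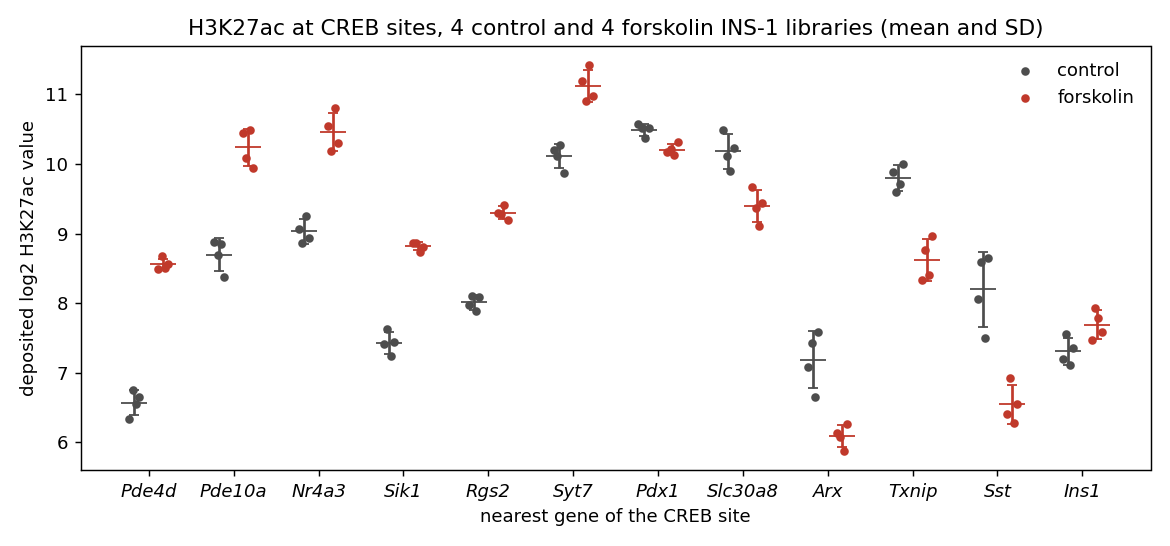
H3K27ac (deposited log2 value, y axis) at 12 CREB sites named by their nearest gene (x axis), with 1 point per library and bars for the mean and SD of 4 control and 4 forskolin INS-1 libraries. The sites were picked for display from the named sites after their values were seen; 7 rose, Pde4d (6.57 to 8.56) and Syt7 (10.11 to 11.12) among them, 5 fell, and the Ins1 site lay 260733 bp from the gene.

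Treated as pairs by replicate number, the same libraries gave 3227 rises and 3190 falls, 6417 in all against 3416. Every site called without pairing was called in the same direction. Rises were 58.2% of the calls; after quantile normalization they were 44.8% (2093 rises, 2577 falls), with no site called in opposite directions. Without the 2 libraries numbered 1, 1960 sites were called. The authors' own table called 3905 sites, of which 3415 were called here in the same direction, and a unit of their log2 fold change corresponded to 0.62 of a unit in these values across sites.

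Immediate targets of CREB, a list fixed in advance, gained H3K27ac at most of their CREB sites. Of 91 sites at 32 genes, 57 rose and 5 fell, with a median log2 change of 0.53; adjusted over the list alone, 61 rose and 5 fell. A site rose at 23 genes, including the regulator of G-protein signalling Rgs2 (promoter, 1.29 ± 0.083 SE), the kinase gene Sik1 (1.39 ± 0.092), the coactivator gene Ppargc1a (1.23 ± 0.11), Klf4 (1.11 ± 0.11) and the nuclear receptor gene Nr4a3 (promoter, 1.43 ± 0.14). The clock gene Per1 rose at 3 sites (1.01, 0.93 and 0.55), the repressor gene Crem at 3 (0.93, 0.92 and 0.67) and Nr4a1 at 2 (0.87 and 0.75). Fos rose at 4 of its 5 sites, by 0.75 just downstream of its start, and the site at −18542 bp had a change of 0.29 (adjusted p = 0.0850; 7.33e-04 with pairing). Sites at 3 genes of the list fell, Sst among them, and 7 genes had no called site. The list ranked above the other sites by camera (adjusted p = 1.41e-13), but adjusted p = 0.378 with an estimated correlation; fry, which asks whether the sites moved together, gave adjusted p = 7.15e-04.

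Genes of beta-cell identity split. Among 57 sites at 21 genes, 10 rose and 15 fell (the same counts adjusted over the list alone; 19 and 26 with pairing), with a median of −0.06; 7 genes had a rise, 10 a fall, and 6 no call. Abcc8, a subunit of the ATP-sensitive potassium channel, rose by 1.01 ± 0.14 (SE) at an intronic site, and sites near the prolactin receptor gene Prlr (0.88 ± 0.12) and the factor gene Foxa2 (0.64 ± 0.093) rose as well. Falls were seen near Chgb (−0.98 ± 0.15), Isl1 (−0.67 ± 0.11) and Hnf1a (−0.46 ± 0.084), and at the promoters of the zinc transporter gene Slc30a8 (−0.79 ± 0.14) and Ero1b (−0.65 ± 0.11). The Pdx1 site, at −5492 bp from its start, fell by 0.29 on the log2 scale (adjusted p = 0.0167). At Ins1, an insulin gene, the promoter change was −0.16 (adjusted p = 0.423; 0.0268 with pairing) and 1 of 5 sites, 260733 bp away, rose by 0.38. No CREB site was nearest to Ins2 or Neurod1. The list as a whole had camera adjusted p = 0.408 and fry adjusted p = 0.0993, or 0.0260 with pairing.

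Genes of the secretion machinery rose more than they fell. Of 46 sites at 21 genes, 18 rose and 2 fell (19 and 3 adjusted over the list alone; 30 and 6 with pairing), with a median of 0.28; 10 genes had a rise, 2 a fall and 10 no call. Syt7, a calcium sensor of exocytosis, rose at 4 of 6 sites, most at an intronic site on chromosome 1, 233408387 to 233412387 (10.11 ± 0.17 to 11.12 ± 0.23, SD, n = 4 each; adjusted p = 1.67e-04). Its promoter had a change of 0.42 (adjusted p = 0.132; 3.21e-05 with pairing). Pam, an enzyme of peptide amidation, rose by 0.97 ± 0.099 (SE), and the promoters of Ptprn (0.75 ± 0.14), Syt4 (0.69 ± 0.10), the SNARE gene Snap25 (0.62 ± 0.13) and Unc13a (0.54 ± 0.12) rose, as did Cpe (0.46 ± 0.095). Rph3al, which encodes a Rab effector, fell (−0.64 ± 0.070). Camera gave adjusted p = 8.66e-04 for the list, but adjusted p = 0.657 with an estimated correlation, and fry gave 0.0183.

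The comparison lists were small. Among hepatocyte and fasting genes 3 of 11 sites rose, near Pah (0.78 ± 0.10, SE), Pck1 (0.55 ± 0.092) and Tat (0.30 ± 0.085), none fell, and the same 3 were called adjusted over the list alone; with pairing 4 rose and 3 fell. The median of this list was −0.03, its mean 0.08 and its camera direction up (adjusted p = 0.699; fry 0.141, or 5.50e-04 with pairing). The second Pck1 site had a change of 0.10 (adjusted p = 0.579), and G6pc had no site. Acinar genes rose at Cpa1 (0.54 ± 0.089) and Cpa2 (0.79 ± 0.23) and fell at the factor gene Bhlha15 (−0.33 ± 0.10), 3 of 5 sites (3 adjusted over the list alone; camera adjusted p = 0.699, fry 0.204, or 0.0125 with pairing). Genes of other islet and vascular cells rose at 7 and fell at 3 of 17 sites (8 and 4 adjusted over the list alone; 10 and 5 with pairing). The receptor gene Kdr (1.77 ± 0.12), Irx1 (1.17 ± 0.11) and Irx2 (0.86 ± 0.082) rose, and Sst, the alpha-cell factor gene Arx (−1.10 ± 0.18) and the Mafb promoter (−0.60 ± 0.10) fell (camera adjusted p = 0.176; fry 0.0130). Of 24 sites at 12 housekeeping genes 1 rose, near Hprt1 (0.42 ± 0.10), with camera adjusted p = 0.699 and fry 0.0574 (0.0260 with pairing). With pairing 5 housekeeping sites rose and 3 fell. The 3 Actb sites had changes of −0.23, −0.24 and −0.31 (adjusted p from 0.0575 to 0.127; from 2.14e-04 to 0.0103 with pairing).

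Some calls ended when libraries were left out. Without the 2 libraries numbered 1, the calls at Unc13a, Tat, Cpa2, Bhlha15, Hprt1, Pdx1, the far Ins1 site, the Fos and Per1 promoters and 1 Crem site ended, with adjusted p from 0.0546 to 0.131 for 3 libraries against 3. Several of the changes stayed about as large there, such as 0.51 at Unc13a, 0.66 at Crem, 0.54 at Per1 and 0.75 at Cpa2. The call at the Fos site 12495 bp away ended without any 1 of the numbers 2, 3 and 4 (adjusted p up to 0.130).

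CREB sites shared with NeuroD1 but not PDX1, both beta-cell transcription factors, had a higher median H3K27ac change than other CREB sites, and the larger group shared with both factors did not. Across the 88 sites with NeuroD1 alone, the median log2 change was 0.22, and 42.0% rose while 22.7% fell. At the 442 sites with both factors the median was −0.05 (25.1% rose, 28.1% fell). It was −0.03 at the 3678 sites with PDX1 alone (17.4% and 13.9%) and −0.0074 at the 6778 sites with neither (17.7% and 11.4%). In that order of classes, 9.09%, 2.26%, 42.4% and 48.4% of sites lay within 1 kb of a gene start, where called sites were fewer. Farther away the medians were 0.25, −0.04, 0.01 and 0.05. The shares that rose or fell were not compared by position. A permutation of class labels among sites (100000 resamples, two-sided) gave p = 1e-05 for the NeuroD1 class, the smallest it can give (adjusted p = 4e-05), and adjusted p from 0.00107 to 0.0440 for the others. Per library, the mean level of the NeuroD1 class relative to all sites went from −0.07 ± 0.023 to 0.05 ± 0.034 (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible; adjusted p = 0.114). The call for sites with both factors ended in 7 of 12 settings that left out a library or a replicate number, with differences from other sites of −0.054 to −0.0035.

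More CREB peaks were called with forskolin than without it in each of 6 INS-1 pairs in which no factor was removed or blocked. Of the pairs left out, that with NeuroD1 knockdown had fewer (4506 and 4057). The pair with A-CREB, which blocks CREB, had more (164 and 1336). Control libraries had 5430 ± 3404 CREB peaks and forskolin libraries 9255 ± 2478 (SD, n = 4 each; two-sided exact permutation p = 0.114). The fold was 10.4 in replicate 1, from 1055 to 10991 peaks, and 1.27, 1.26 and 1.26 in replicates 2, 3 and 4. It was 1.68 with a GFP virus and 1.06 with a control RNA interference virus (USi). Over the 6 pairs the mean log2 difference was 0.87 (exact sign-flip p = 0.0313, the smallest 6 pairs allow). Without the replicate 1 pair it was 0.37 (exact sign-flip p = 0.0625, the smallest 5 pairs allow). H3K27ac peaks numbered 28210 ± 1960 and 31329 ± 4728 (exact permutation p = 0.286). They were more with forskolin in 7 of 7 pairs without a removed factor or an inhibitor, by a mean fold of 1.08 (exact sign-flip p = 0.0156, the smallest possible). Of the pairs left out, that with A-CREB had fewer (26160 and 25159). Those with JQ1, A485, NeuroD1 knockdown or a deleted Syt7 enhancer had more. Over the 8 CREB libraries, peak number and depth had Pearson r = 0.53 (permutation p = 0.185; adjusted p = 0.260 over 4 relations) and Spearman rho = 0.19 (p = 0.665; adjusted p = 0.665), and r = −0.06 without the 2 libraries farthest from the median depth. Peak number and the percent of tags in peaks, which is summed over the same peaks, had r = 0.863 (permutation p = 0.00516, adjusted p = 0.0206; rho = 0.738, adjusted p = 0.183). Within pairs the percent of tags in peaks often fell with forskolin while peak number rose. It went from 3.14 to 2.73, 3.47 to 2.92 and 6.06 to 5.25 in replicates 2, 3 and 4, and from 2.86 to 2.24 with USi. In replicate 1 (0.37 to 4.27) and with the GFP virus (1.92 to 2.35) it rose.

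**Figure D2:**
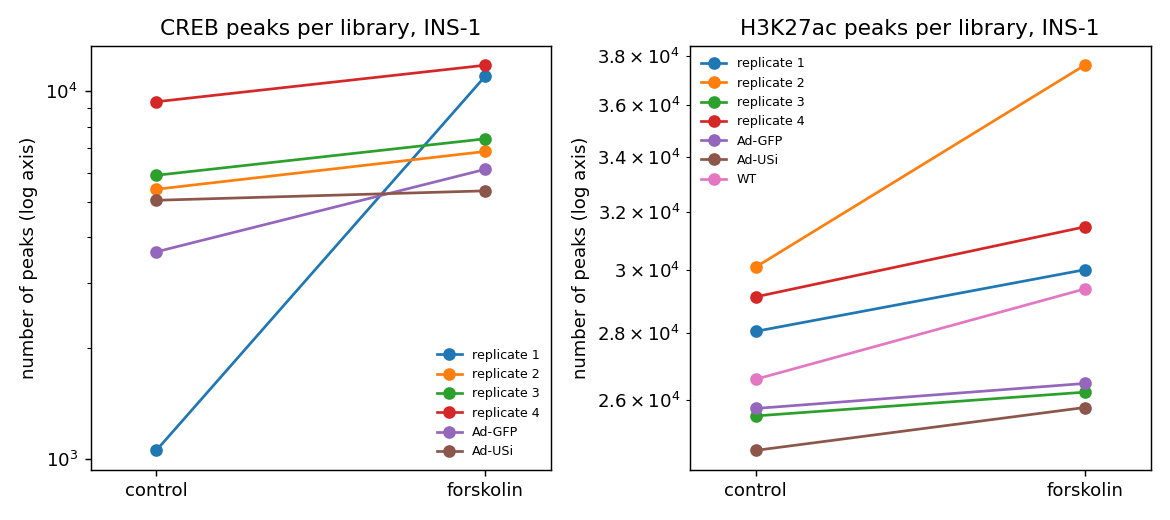
Number of CREB peaks (left) and H3K27ac peaks (right) per INS-1 library on log axes, with a line joining the control and forskolin library of each pair. All 6 CREB lines and all 7 H3K27ac lines go up, and the steepest CREB line is replicate 1 (1055 to 10991).

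At enhancers that the study classed as inducible, CREB peaks were less frequent before forskolin than after it, to an extent that varied between control libraries. The study made this set of 741 windows, and a noninducible set of 3390, from these H3K27ac libraries at CREB peaks of forskolin replicate 1, so they are not independent evidence for CREB or H3K27ac. The sets do not follow from the rule stated for them alone: 1213 table sites meet the inducible rule, 728 of them in the set. Of the 3406 table sites in the noninducible set, 2749 meet its rule. CREB occupied 27.9% ± 21.2 of inducible windows in control and 96.1% ± 4.11 in forskolin libraries (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0457 over 8 comparisons). The control libraries ran from 4.32% in replicate 1 to 55.2% in replicate 4, and the forskolin libraries from 90.3% to 99.9%. At noninducible windows the shares were 69.8% ± 34.2 and 94.2% ± 5.26 (exact permutation p = 0.0857), a difference of 24.4 points. It was 7.60 points without control replicate 1, the lowest control library (exact permutation p = 0.171), and 32.95 points without control replicate 4, the highest (p = 0.0286). H3K27ac peaks covered 76.6% ± 2.15 and 98.7% ± 0.42 of inducible windows (exact permutation p = 0.0286; adjusted p = 0.0457) and 97.7% and 98.0% of noninducible windows (p = 0.343; 0.0286 without forskolin replicate 3). With an overlap rule of centres within 500 bp, the H3K27ac difference at inducible windows was 2.80 points (exact permutation p = 0.429).

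CRTC2, the cAMP-regulated coactivator of CREB, had peaks at more enhancers of both sets with forskolin, with the larger gain at inducible ones. It had a peak at 11.2% of inducible windows in control cells and 97.7% (interval 96.4 to 98.6) with forskolin, against 40.9% and 81.4% of noninducible windows, as its peaks went from 3941 to 17827. The odds ratio of inducible over noninducible windows went from 0.182 to 9.76 (Fisher's exact test across windows, adjusted p = 3.94e-60 and 8.23e-38). At the site nearest each gene of the CREB target list, CRTC2 was gained at 12 of 31 genes, including Nr4a2, Nr4a3 and Crem, kept at 15, such as Fos and Sik1, and present in neither arm at 4. It was also gained at Pdx1, Pax6 and Slc30a8, at Snap25 and Syt4, and at Pck1 and Tat, and was lost at the nearest site of Syt7 and Vamp2. Both CRTC2 libraries were shallow, with 7.85 and 8.62 M tags.

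BRD4 peaks were found at more inducible enhancers with forskolin in 3 experiments, while noninducible enhancers had fewer in replicate 1 and more in the other pairs. In replicate 1 its peaks covered 63.6% of inducible windows in control cells and 95.3% with forskolin, against 86.4% and 63.3% of noninducible windows. The latter went with a general fall in that experiment, from 55.9% to 39.1% of all H3K27ac peaks and from 13.7% to 6.99% of tags in peaks. The odds ratio went from 0.275 to 11.7 (Fisher's exact test, adjusted p = 3.19e-42 and 4.51e-82). Replicate 2 had 690 peaks in control cells, at 1.89% of inducible windows, and 12396 with forskolin, at 79.2%, while noninducible windows went from 6.84% to 47.8%. With a GFP virus the shares went from 27.5% to 90.3% and from 67.1% to 73.5%. The replicate 1 lists were called in HOMER's histone style and the others in its factor style, so their peak numbers are not compared. Of the putative peaks of replicate 2, the comparison with input removed 94.6% of 13437 in control cells and 41.3% of 22790 with forskolin. How much of the gain in replicate 2 came from that step was not tested. In replicate 2, with many more peaks in the forskolin list, BRD4 was gained at 10 of 31 CREB target genes, such as Fos, Junb, Nr4a1 and Crem. BRD4 was also gained there at 6 of 11 housekeeping genes, such as Actb. It was gained at Pdx1 and Vamp2, kept at Ins1 and Syt7, and lost at Sst, Iapp, Kcnj11 and Cplx2. CBP, a histone acetyltransferase bound by CREB, had few peaks (1380 and 1028), at 2.56% and 5.26% of inducible windows and at 9.82% and 8.20% of noninducible windows. NeuroD1 peaks covered 5.13% of inducible windows in control cells and 12.8% with forskolin, and 3.60% and 3.54% of noninducible windows (odds ratio 1.45, adjusted p = 0.0732, and 4.01, adjusted p = 6.49e-20). With centres within 500 bp the control odds ratio was 1.53 (adjusted p = 0.0471). PDX1, measured with forskolin and a control virus, covered 64.2% and 49.2% (odds ratio 1.85).

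**Figure D3:**
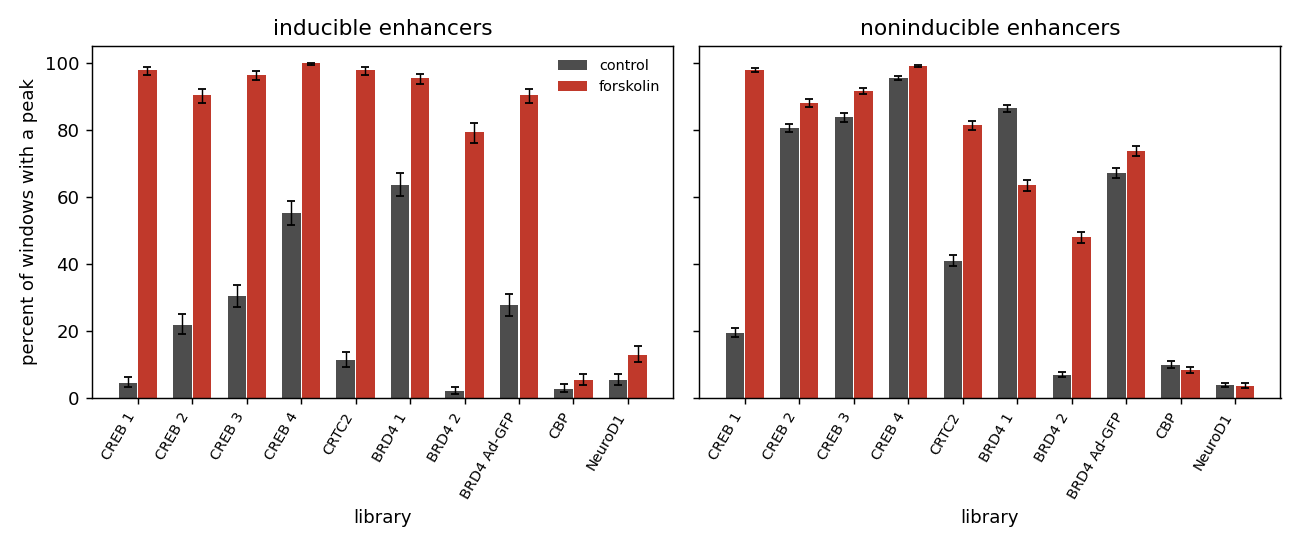
Percent of 741 inducible (left) and 3390 noninducible (right) enhancer windows with a peak in each INS-1 library, with 95% Wilson intervals for counting error; dark bars are control libraries and red bars forskolin libraries. CRTC2 goes from 11.2% to 97.7% of inducible windows, and BRD4 replicate 1 falls from 86.4% to 63.3% of noninducible windows.

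A-CREB, a dominant-negative protein that blocks CREB from binding DNA, removed most CREB peaks and the forskolin gain of H3K27ac peaks at inducible sites. With the GFP virus CREB had 3656 peaks in control cells and 6130 with forskolin, and with A-CREB 164 and 1336. At the 730 inducible CREB sites the CREB share went from 14.5% to 71.8% (interval 68.4 to 74.9) with GFP, and from 0 (upper bound 0.523%) to 2.33% (1.46 to 3.70) with A-CREB. H3K27ac peaks at these sites went from 60.8% to 93.6% (91.5 to 95.1) with GFP and from 53.4% to 54.1% (50.5 to 57.7) with A-CREB. At the 3406 noninducible sites they covered 96.2% and 96.9% with GFP, and 95.6% and 95.04% with A-CREB. BRD4 with forskolin was at 69.2% of inducible sites with GFP and 35.8% with A-CREB, but at 49.2% and 63.7% of noninducible sites, where the A-CREB library had 23275 peaks against 16312. In forskolin-treated cells A-CREB removed the CREB peak nearest to Fosb, Junb, Nr4a1 and Nr4a2 and left those of Fos, Per2, Sik1 and Dusp1. Of 25 CREB target genes with a CREB peak, 18 lost it, as did 12 genes of the secretion list, Snap25 and Vamp2 among them, and 11 beta-cell genes, such as Isl1 and Chga. Of 9 housekeeping genes with a peak, 6 lost it, Gapdh and Tbp among them, so the loss was not particular to these lists. Among CREB target genes H3K27ac was lost at 4, Nr4a1, Nr4a2, Rgs2 and Nfil3, and kept at 26. It was kept at all 20 beta-cell genes and all 11 housekeeping genes. Of 6 hepatocyte and fasting genes 3 lost it, as did 2 of 4 acinar genes, so this loss was not particular to CREB targets. Each arm had 1 library, so the difference between viruses was not tested. With at least 50% overlap the BRD4 difference at inducible sites was 18.9 points. With lists drawn at random to equal length the CREB difference there was 13.6 points. The draw alone lowers the share of the longer list, so it is no check on a loss of peaks.

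**Figure D4:**
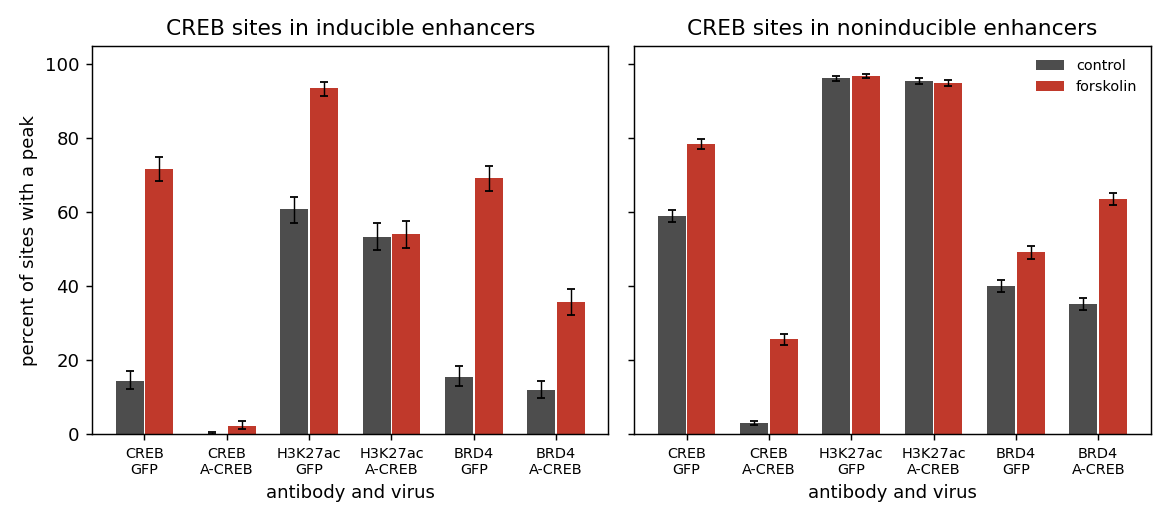
Percent of CREB sites in inducible (730 sites, left) and noninducible (3406 sites, right) enhancers with a CREB, H3K27ac or BRD4 peak, in INS-1 cells with a GFP or A-CREB virus, 1 library per bar with 95% Wilson intervals for counting error. The H3K27ac share at inducible sites goes from 60.8% to 93.6% with GFP and from 53.4% to 54.1% with A-CREB.

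Inhibition of the acetyltransferases p300 and CBP with A485 (10 µM, 3 hours) left BRD4 at fewer forskolin-inducible enhancers than its untreated library had, and inhibition of BET bromodomains with JQ1 (1 µM, 3 hours) left it at most of them. BRD4 was at 79.2% of inducible windows with forskolin alone in replicate 2 and at 21.7% (18.9 to 24.8) with A485. At noninducible windows these shares were 47.8% and 32.1%, as peaks went from 12396 to 4674. In replicate 1 BRD4 was at 95.3% of inducible windows with forskolin alone and 81.8% (78.8 to 84.4) with JQ1. At noninducible windows these shares were 63.3% and 52.2%. Peaks went from 13659 to 11151 with JQ1, and tags in peaks from 6.99% to 3.53%. A window that kept a peak therefore need not have kept its level of BRD4. Without forskolin, JQ1 took BRD4 from 63.6% to 18.6% of inducible windows and from 86.4% to 50.3% of noninducible windows. At the 584 super-enhancers of forskolin cells, clusters of strong enhancers, BRD4 was at 96.6% with forskolin alone and 56.8% with A485, and at 99.5% and 96.7% in the JQ1 experiment. A485 removed the forskolin BRD4 peak nearest to Fos, Nr4a1, Sik1 and Pde4d and to Pdx1 and Syt7. It left those of Junb, Crem, Ins1 and Isl1. Of 31 CREB target genes, 7 lost the peak with A485, 3 kept it, 7 gained one and 14 had none in either library. JQ1 removed those of Nr4a3, Gem and Maff and left Fos, Fosb, Junb, Ins1, Pdx1 and Syt7. H3K27ac peaks at inducible windows went from 74.4% to 98.4% with forskolin under JQ1 and from 50.2% to 81.2% under A485. There was 1 library per arm and no test. With lists drawn at random to equal length the untreated minus JQ1 difference was −4.99 points and the untreated minus A485 difference 15.5 points. The draw alone lowers the untreated shares, so these values cannot show whether the inhibitors removed peaks. The inhibitor experiments also differed in peak-calling style, so the difference between them was not tested.

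With NeuroD1 knockdown, CREB peaks were lost more often at sites that CREB shared with NeuroD1 than at sites with neither factor. NeuroD1 itself went from 4731 to 167 peaks in the knockdown library, which checked the label. With forskolin, 59.1% (52.0 to 65.8) of the CREB peaks at NeuroD1 sites were lost, against 30.1% (28.5 to 31.9) at sites with neither factor (odds ratio 3.34, Fisher's exact test across sites, adjusted p = 4.46e-15). Without forskolin the shares were 63.6% and 17.2% (odds ratio 8.40, adjusted p = 3.49e-18). H3K27ac peaks were lost at 11.5% and 2.27% of such sites with forskolin (odds ratio 5.60, Fisher's exact test, adjusted p = 1.09e-19). Without it the shares were 3.68% and 4.46% (adjusted p = 0.481). The classes already differed with the control virus. Without forskolin CREB was at 7.95% of sites with NeuroD1 alone, 15.8% with both factors and 39.5% with neither. Only 9.09% and 2.26% of the first 2 classes lay within 1 kb of a gene start, against 48.4% of the last. Whether peak strength or position accounts for the difference in loss was not tested. CREB peaks nearest to Fos, Fosb, Fosl2 and Junb were kept in forskolin cells, and those of Iapp, Scg2, Gipr and Hnf1a, of Vamp2 and Pam, and of Pck1 were lost. Of 25 CREB target genes with a peak, 24 kept it and Per2 lost it. Of beta-cell genes, 7 kept a peak, 4 lost it and 1 gained one. Of secretion genes, 9 kept a peak, 2 lost it and 2 gained one. The NeuroD1 loss itself was lower at NeuroD1 sites (86.3% of peaks) than at sites with neither factor (98.1%; odds ratio 0.119), and with lists of equal length that odds ratio was 1.33 (Fisher's exact test, p = 1).

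With PDX1 knockdown, CREB peaks were not lost more often at PDX1 sites. PDX1 peaks went from 11363 to 5711 with forskolin. CREB peaks were lost at 11.3% (10.23 to 12.404) of PDX1 sites and 14.5% (13.6 to 15.6) of sites with neither factor (odds ratio 0.747, adjusted p = 3.22e-05), and H3K27ac peaks at 2.11% and 2.58% (odds ratio 0.815, adjusted p = 0.162). PDX1 peaks were lost at 48.0% and 60.3% of the same classes (odds ratio 0.609, Fisher's exact test, adjusted p = 4.31e-09; 0.602, p = 0.249, with at least 50% overlap). All 27 CREB target genes with a CREB peak kept it, Fos and Junb included, and Bdnf and Vgf gained one. Peaks nearest to Pax6, Ero1b, Syt7, Cplx2, Scg3 and Pam were lost. Of beta-cell genes, 13 kept a peak, 2 lost it and 1 gained one. Of secretion genes, 14 kept a peak and 4 lost it. Only the forskolin arm was measured.

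In AR42J acinar cells, which were given NeuroD1 or GFP by virus, CREB peaks were more frequent at INS-1 NeuroD1 sites with NeuroD1. It was at 11.4% of the 88 INS-1 sites shared by CREB and NeuroD1 with GFP and at 29.5% with NeuroD1. At the 442 sites that also held PDX1 the shares were 14.3% and 31.2%, and at sites with neither factor 60.7% and 63.1%. Of NeuroD1 sites without a CREB peak in GFP cells, 21.4% (17.9 to 25.4) gained it, against 13.6% (12.37 to 14.97) of sites with neither factor (odds ratio 1.73, Fisher's exact test across sites, adjusted p = 3.16e-05). H3K27ac peaks were gained at 27.4% and 12.3% in control cells (odds ratio 2.69, adjusted p = 2.16e-11) and at 28.99% and 7.58% with forskolin (odds ratio 4.98, adjusted p = 3.03e-24). All peaks together numbered 17572 and 19354 for CREB, and the NeuroD1 library of that comparison was deeper (35.0 M tags against 25.4 M). With centres within 500 bp the forskolin H3K27ac odds ratio was 1.15 (Fisher's exact test, p = 0.294), and the NeuroD1 library there held 10.1 M tags against 27.97 M for GFP.

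Most CREB peaks of mouse islets were also found in hepatocytes, while hepatocytes held many of their own. Islet control cells had 8758 CREB peaks, of which 73.7% (72.8 to 74.6) met a hepatocyte peak, and hepatocytes had 20255, of which 31.9% (31.2 to 32.5) met an islet peak. Islet CREB peaks lay in H3K27ac peaks of islets in 92.7% of cases and hepatocyte CREB peaks in those of hepatocytes in 77.8%. Shared peaks of hepatocytes had H3K27ac more often than those restricted to hepatocytes (92.7% against 70.8%; odds ratio 5.22, Fisher's exact test across peaks), and so did those of islets (94.6% against 87.4%; odds ratio 2.51, adjusted p = 6.68e-27). With forskolin islets had 6949 CREB and 487 CRTC2 peaks against 8758 and 321 in control cells, and hepatocytes 19495 and 8353 against 20255 and 8956. H3K27ac peaks went from 31743 to 30304 in islets and from 36011 to 32868 in hepatocytes. With lists drawn at random to equal length, 31.9% of islet CREB peaks met a hepatocyte peak. That draw removes hepatocyte peaks at random and so lowers the share by itself. No mouse gene table was used here, so the mouse peaks are not given gene names.

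RNA polymerase II peaks covered less of the Syt7 region in cells labelled as lacking an enhancer of that gene (SYT7eDel) than in wild-type cells. Within 100 kb of the Syt7 start (chromosome 1, 233382666, rn5), wild-type cells had polymerase peaks over 23676 bp in control and 62945 bp with forskolin, and deleted cells over 7397 bp and 16438 bp. In wild-type forskolin cells a single peak ran from 233421971 to 233450605. Deleted cells had 31.2% of the wild-type covered length in control and 26.1% with forskolin; within 50 kb these shares were 18.97% and 7.78%, and within 200 kb 84.1% and 56.3%. Genome-wide the deleted cells had more polymerase peaks, 19063 and 24786 against 17114 and 19305. H3K27ac in cells without a virus covered 45417 to 55808 bp around Syt7 in 4 control libraries and 67475 to 99994 bp in 4 forskolin libraries. H3K27ac of the deleted and wild-type cells was given on another rat build and was compared genome-wide only, where 93.0% of wild-type control peaks and 91.2% of wild-type forskolin peaks met a peak of the deleted cells. There was 1 library per arm and no test.

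Gene sets made by the study lay near inducible enhancers to differing extents. Within 100 kb of a gene start, an inducible CREB-bound enhancer was found for 53.7% of 190 forskolin-induced genes, 63.5% of 230 BRD4-induced genes and 7.70% of 1402 BRD4-repressed genes (odds ratios against the last set 13.9 and 20.8, Fisher's exact test across genes, adjusted p = 2.31e-48 and 4.26e-76). For CREB targets in super-enhancers the share was 63.2% of 136 genes, and for those driven by promoters 51.2% of 41. Noninducible enhancers lay near 59.3% of BRD4-repressed genes, 35.8% of forskolin-induced genes and 30% of BRD4-induced genes. Super-enhancers of forskolin cells lay near 77.2% of CREB targets in super-enhancers, against 23.3% of BRD4-repressed genes. They lay near 39.5% of forskolin-induced genes (odds ratio 2.15, Fisher's exact test, adjusted p = 9.94e-06). For CREB targets driven by promoters the share was 34.1% (adjusted p = 0.156) and for BRD4-induced genes 29.1% (adjusted p = 0.0700). Within 10 kb the tests of promoter-driven and BRD4-induced genes passed, with odds ratios of 2.28 (adjusted p = 0.0353) and 1.58 (adjusted p = 0.0241), and promoter-driven genes had fewer noninducible enhancers than BRD4-repressed genes (0.225, adjusted p = 0.00235). Forskolin-induced and BRD4-induced genes shared 51 members, where 2.36 would be shared by chance among 18539 genes (adjusted p = 2.72e-53). The sets were not disjoint: BRD4-repressed genes shared 34 members with BRD4-induced genes (17.4 by chance, odds ratio 2.15, adjusted p = 3.51e-04) and 23 with forskolin-induced genes (14.4 by chance). The study chose these sets itself, so they are not independent evidence of direction.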

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

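All tests of this part were chosen after the result was seen, except the comparison of H3K27ac at kept and lost BRD4 peaks. Some INS-1 libraries lay far from the other 3 of their group. CREB forskolin replicate 4 had a median peak width of 233 bp, H3K27ac control replicate 3 a median width of 1542 bp, and H3K27ac forskolin replicate 1 had 61.7% of its tags in peaks. H3K27ac forskolin replicate 3 had peaks at 92.0% of all CREB sites and 97.1% of noninducible enhancers. These were 5 of 36 groups examined, and chance sets apart about 1 group in 20. At named sites 6 of 174 groups had such a library. The log2 values were 6.10 for Tgds in control 2, 7.39 for Chgb in forskolin 3, 9.56 for Isl1 in control 3, 7.42 for Pah in control 4, 9.01 for Pck1 in forskolin 4 and 8.95 for Irx2 in control 2.

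Final peak numbers moved in opposite directions between mouse cells and the INS-1 pairs without a removed factor or an inhibitor, except for CRTC2 in islets. The difference was not tested. Putative peaks of hepatocytes, before the final lists, were more with forskolin: 36439 and 37268 for CREB, 19664 and 20886 for CRTC2, and 558423 and 623707 for H3K27ac. The log2 ratio of forskolin over control CREB peaks was −0.33 in islets and −0.055 in hepatocytes, against 0.09 to 3.38 in 6 INS-1 pairs. The INS-1 pair with NeuroD1 knockdown, not among these, also fell, from 4506 to 4057 peaks. For H3K27ac the log2 ratio was −0.067 in islets and −0.13 in hepatocytes, against 0.04 to 0.32 in 7 INS-1 pairs. The INS-1 pair with A-CREB, not among these, fell as well, from 26160 to 25159 peaks. Both AR42J pairs also fell, from 50736 to 50029 with GFP and from 57068 to 47179 with NeuroD1. For CRTC2 the log2 ratio was −0.10 in hepatocytes, 0.60 in islets and 2.18 in INS-1 cells.

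CRTC2 peaks were also seen in data outside the planned comparisons, at beta-cell factor sites that the study classed as without CREB. With forskolin CRTC2 was at 31.97% of NeuroD1 sites (1.86% in control cells), 57.3% of sites with both NeuroD1 and PDX1 (3.66%) and 34.9% of PDX1 sites (4.59%), from 1 library per arm and untested. All CRTC2 peaks together went from 3941 to 17827, and the putative peaks removed by input from 73.1% to 43.7%. Whether the rise was particular to the beta-cell factor sites was not tested. These sites were not free of CREB: with forskolin, CREB peaks lay at 4.65% to 18.2%, 5.42% to 22.6% and 5.66% to 17.1% of them in 4 libraries.

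More CREB peaks were called with forskolin in each of 6 INS-1 pairs in which no factor was removed or blocked, though not with NeuroD1 knockdown (4506 and 4057). A low yield of control replicate 1 does not account for all of this, since the other 5 pairs had a mean log2 difference of 0.37 (0.366). The comparison of each arm with its own input, a separate library per the file headers, may account for it: before that step, only 2 of 6 pairs had more putative peaks with forskolin. The percent of putative peaks removed by input was smaller with forskolin in 6 of 6 pairs. Whether CREB binding itself rose genome-wide is therefore left open.

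BRD4 peaks shifted towards inducible enhancers. The number of peaks called does not account for the gain at inducible enhancers, since in replicate 1, where peaks fell from 19501 to 13659, their share still went up by 31.7 points, but the fall at noninducible enhancers went with that general fall. Loss of H3K27ac at the same sites could not be judged: the median change was −0.09 at 1770 kept and −0.10 at 1039 lost BRD4 peaks, a difference of 0.0140 (0.0026 to 0.0275). The bound of 0.1 was set before this value was seen, but noninducible sites span only −0.19 to −0.02 between quartiles, so a larger difference was hard to reach. That reason was set after the value was seen.

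Among the 35 splits of the 8 H3K27ac libraries, 1 of 35, the real one, gave as many called sites (3416); the highest other (422) set numbers 1 and 3 against 2 and 4 and parted no pair. Since same-numbered libraries were alike, the fair comparison is with the 8 splits that part all 4 pairs, of which the others called 0 sites, but 8 are too few for a share under 0.05. Other scalings kept at least 2438 of the called sites in the same direction, so scaling is not the whole cause. For the CREB target list 1 of 35 splits gave a camera p as small (best other 1.15e-12). For the secretion list 10 of 35 did (best other 2.81e-08), and 3 of the 8 that part all pairs (best other 1.12e-04, real 2.47e-04); chance was not excluded, though most of the others set 3 libraries of an arm against 1 and so carry part of the treatment difference.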

How the results depend on the processing

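Of 2033 results under alternatives, 1910 kept their direction, call and size, 69 were weaker, 29 stronger, 22 moved and 3 reversed; no named site reversed, and 12 of 76 called sites lost their call in at least 1 alternative. With the replicate block, 6417 sites were called and 8 named sites gained a call. Beyond these and the list tests named in the report, the block changed no other call where it was run; it was not run for the co-bound classes or the shares of enhancers. For peak numbers the same-numbered pairs gave exact sign-flip p = 0.125, the smallest 4 pairs allow, while the report's tests over 6 and 7 pairs, which add libraries, passed. Requiring a change of at least the log2 of 1.5 in these values left 1282 sites, 78.5% of them rises. Quantile normalization, added after the data were seen, turned the majority of calls from rises to falls (44.8% rises). For each of these changes the cause was not tested.

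With an estimated correlation the camera adjusted p was 0.378 for CREB targets and 0.657 for the secretion list. Leaving out libraries gave 1960 to 3249 called sites, differences of −0.054 to −0.0035 for the class with NeuroD1 and PDX1, and log2 CREB peak differences of 0.33 to 1.48. The CREB share of noninducible enhancers differed by 7.60 to 32.95 points and the H3K27ac share by 0.243 to 0.666 points. Over the CREB pairs, leaving out replicate 1, 2, 3 or 4, the GFP or the USi pair gave 0.366, 0.974, 0.977, 0.977, 0.893 and 1.03, all exact sign-flip p = 0.0625, since 5 pairs allow no smaller.

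Overlap rules and list lengths moved single-library results. Drawing a longer list at random lowers its shares by itself, so equal lists are no check on a loss of peaks. The cause of the other moves was not tested. The H3K27ac difference at inducible enhancers was 2.80 points with centres within 500 bp. For A-CREB at inducible sites, GFP minus A-CREB was 63.7 (50% overlap) and 13.6 (equal lists) for CREB, 29.2 (centres) and 34.1 (equal lists) for H3K27ac, and 18.9, 39.7 and 43.7 (overlap, centres, equal lists) for BRD4. The untreated minus JQ1 difference was 1.48 with centres and reversed to −4.99 with equal lists, and for A485 it was 15.5 with equal lists. The odds ratio of NeuroD1 control peaks was 1.53 with centres, that of NeuroD1 loss in its own knockdown reversed to 1.33 with equal lists, that of PDX1 loss was 0.602 with 50% overlap, and that of AR42J H3K27ac with forskolin was 1.15 with centres. Islet CREB peaks shared with hepatocytes were 69.9%, 77.5% and 31.9%, and hepatocyte peaks shared with islets 30.2% and 33.8%. Within 10 kb, gene-set odds ratios were 0.225, 1.58 and 2.28. Deleted cells had 18.97% and 7.78% of the wild-type polymerase length at Syt7 within 50 kb, and 84.1% and 56.3% within 200 kb, in control and forskolin cells.

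Methods chosen before the data were examined that need counts (DESeq2, other scalings of counts, low-count filters and pseudocounts) were not run, since the values were on a log2 scale. A list restricted to peaks with high scores and the mouse promoter distance were not run either. The limit that depth sets was not tested.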

Other observations

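Super-enhancer lists of 1 control and 1 forskolin INS-1 library differed in part, and H3K27ac at CREB sites within them changed in the same direction. With 1 list per arm, how far lists of the same arm would differ is not known. Of 606 control and 584 forskolin super-enhancers, 405 and 399 met one of the other arm. Of 374 CREB sites in the 185 found only with forskolin, such as those of Fosb, Nr4a3, Crem and Sik1, 57.5% rose in H3K27ac and 0.802% fell (median log2 change 0.46). Of 246 sites in the 201 found only in control cells, such as those of Slc30a8 and Ldlr, 0.813% rose and 49.2% fell (median −0.28). In the 399 found in both, such as those of Ins1, Pdx1 and Syt7, 18.9% of 1031 sites rose and 13.1% fell. Super-enhancers were defined on replicate 1 of the same H3K27ac libraries, so this is not independent evidence. Without the libraries numbered 1, 43.6% of sites rose in the forskolin-only group and 28.9% fell in the control-only group.

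Sites of beta-cell factors that the study classed as without CREB had H3K27ac peaks less often with forskolin in each of 4 pairs, but no class passed the test after adjustment. CREB peaks lay at up to 17.2% of the sites with both factors in control libraries and up to 22.6% with forskolin. At 738 sites with NeuroD1 and PDX1 the share went from 85.2% ± 2.63 to 75.5% ± 4.00 (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0857), and at 538 NeuroD1 sites from 80.9% ± 0.18 to 77.5% ± 3.68 (same p-values). At 9929 PDX1 sites it was 67.1% and 65.0% (exact permutation p = 0.457). These tests did not use the pairing by replicate number, and 4 pairs allow no exact sign-flip p under 0.125. BRD4 replicate 1 was at 83.6% and 51.6% of the sites with both factors, and replicate 2 at 5.28% and 24.3%.

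The readme lists the raw file of H3K27ac control replicate 3 among the forskolin files as well. The values of that library correlated with the other control libraries at 0.978 to 0.990, and no site had identical values in any 2 of the 8 libraries.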
